A study of Homo sapiens with 16 samples.

How the data were processed

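The series holds 16 arrays of total RNA from human monocyte-derived macrophages, which are blood monocytes grown in culture until they take on macrophage form. Per the labels' protocols, the cells were grown for 7 days in medium alone or with 4F, a short peptide that mimics apolipoprotein A-I, in a fixed amount per cell number. Cells of both kinds were then left as they were or given lipopolysaccharide (LPS), a bacterial cell wall component, at 1 µg/mL for 18 h. This made 4 groups of 4 arrays, named control, 4F, control+LPS and 4F+LPS below. RNA was isolated with a kit that also recovers small RNA and was prepared and biotin-labelled by the Affymetrix procedure, per the labels' protocols.

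The deposited table gave 1 log2 value for each of 28869 probe sets on each array, with 0 missing values and a range from -4.91 to 6.1. Within every probe set the mean of the 4 control arrays was 0 to within 1.19e-06, so the authors had set each value relative to the control group before deposit. The base of the logarithm was taken as 2. The base, the summarization of probes, the normalization between arrays, the filter and the software are not given in the sources used here. Subtracting 1 constant per probe set leaves every difference between groups as it was, but it removes the absolute signal. Dim probe sets could therefore not be told from bright ones, and the planned filter on dim probe sets and the planned choice of the brightest probe set per gene could not be applied. All genes were tested, and a gene measured by more than 1 probe set was given their mean. For arrays the number per group limits the precision, and no signal over background could be computed from centred values.

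Probe sets were named through the platform annotation and the current gene table given with the data. Of the 28869 probe sets, 19310 named 1 gene, 1752 named several and 7807 were unnamed here; 19279 of the first kind matched the gene table. The 25 probe sets on the Y chromosome or of X-inactivation transcripts were left out. This left 18353 genes, of which 684 had more than 1 probe set.

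Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) to all 16 arrays, with 1 residual spread per gene shared by the 4 groups, 12 residual degrees of freedom and a prior of 4.35 degrees of freedom. Tests were two-sided. Benjamini-Hochberg adjustment ran over the 18353 genes within each of 5 comparisons, and a gene was called at an adjusted p under 0.05. The 5 comparisons were 4F without LPS (4F minus control), 4F with LPS (4F+LPS minus control+LPS), LPS in control cells, LPS in 4F cells, and the difference between the last 2. Values are log2 fold changes ± the standard error of the fit (SE) unless another error is named, and n is 4 arrays per group throughout. The labels do not say whether the 4 arrays of a group came from separate cultures or donors, so p-values measure only the spread between these arrays, which may be technical. The arrays without LPS and those with LPS carry different kinds of submitter codes. Whether these mark a batch is not stated, and such a batch could not be told apart from LPS.

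Before the data were examined, 35 gene lists with 733 members were fixed, of which 663 members were measured. They covered pattern recognition receptors, immune signalling, lipid metabolism, stress, macrophage state and markers of other cell types. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 35 lists of a comparison, and again with an estimated correlation. The same tables hold limma's fry. The genes named were fixed by a rule: every measured Toll-like receptor gene with CD14, LY96 and MYD88, the 10 largest changes in each direction among called genes whose 2 groups of arrays did not overlap (with no such condition for the difference of LPS responses), and up to 4 called members of each list with the smallest adjusted p, or where none was called up to 2 with the smallest p. The text names genes from the top of each part. Genes with common inherited differences between people were left out of naming, and 13 of these that were measured were examined only as a set. Classes of genes used as technical measures (olfactory receptor, keratin-associated protein and small RNA genes) were drawn up after a first look at the values.

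The fit was tested on simulated data made from the real spread of 18353 genes. With 1 spread shared by all groups, false calls made up 4.55% of calls for 4F without LPS, 7.07% for 4F with LPS, 6.74% for LPS in control cells and 5.95% for LPS in 4F cells. With each group given its own spread, the corresponding shares were 7.25%, 42.6%, 25.5% and 20.3%, and 12.6%, 8.62%, 9.63% and 9.38% for a fit of the 2 groups alone. In these simulations the shared spread therefore understated the error in comparisons that involve the more variable LPS groups. The simulation changed only a small part of the genes and drew each gene and each array independently. It also took the SD of 4 arrays as the true spread of a group, which can exaggerate differences in spread between groups. For 4F with LPS 135 of 317 simulated calls were false, while the data called 12560 genes. The shares are therefore not the false share of the real calls. Changes of 1 log2 unit were recovered in 94.1% to 100.0% of the simulated genes and changes of 0.5 in 63.6% to 83.6%.

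Alternatives chosen before the data were examined were a fit of the arrays of the comparison alone, eBayes with a trend, array weights, quantile normalization of the centred values over all probe sets, centring of each array on its median, every probe set tested on its own, a minimum change of 1.5-fold, an adjusted p under 0.01, the replicate number as a block, and each array left out in turn. A further 4 alternatives were chosen after the data were seen: the median of the olfactory receptor genes of each array as a covariate, leaving out 4F+LPS replicates 3 and 4, leaving out 4F+LPS replicates 1 and 2, and a camera test against listed genes only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.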

Results

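Transcripts of 18353 genes were compared on 16 arrays of human monocyte-derived macrophages, with 4 arrays each of cells grown in medium (control), cells grown with the peptide 4F, control cells given LPS (control+LPS) and 4F cells given LPS (4F+LPS). The series title names the regulation of pattern recognition receptors, the proteins by which cells sense microbial molecules, by 4F. All values are relative to the mean of the control arrays. The first principal component held 44.6% of the variance and the second 25.7%. The median standard deviation of a gene between the arrays of a group was 0.10 for control, 0.07 for 4F, 0.14 for control+LPS and 0.14 for 4F+LPS on the log2 scale. The 4F+LPS arrays had correlations across genes from 0.551 to 0.882 with one another, against 0.928 to 0.952 for 4F. They fell into pairs, with 0.866 for replicates 1 and 2, 0.882 for replicates 3 and 4, and 0.551 to 0.607 across the pairs. If arrays of a pair were not independent, n = 4 overstates the replication of 4F+LPS. Leaving out 1 array at a time would not show this.

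Growth with 4F without LPS raised genes of matrix, macrophage maturation and lipid handling. The largest increases were in FN1 (fibronectin, 5.34 ± 0.64, adjusted p = 1.91e-05), SPP1 (osteopontin, 4.72 ± 0.87), CHIT1 (an enzyme of mature macrophages, 4.20 ± 0.71), DCSTAMP (a mediator of macrophage fusion, 3.68 ± 0.70) and MMP12 (macrophage elastase, 3.53 ± 0.62). Their SE rests on the spread shared by all groups, which includes 4F+LPS. There the SD was 1.96 for FN1, 2.49 for SPP1, 2.02 for CHIT1 and 2.01 for MMP12. In control it was 0.58, 1.12, 0.06 and 0.23, and in 4F 0.005, 0.09, 0.23 and 0.16. The largest decreases were in THBS1 (thrombospondin 1, -3.10 ± 0.41), PPBP (a platelet chemokine, -2.94 ± 0.25), the small nucleolar RNA SNORA80E (-2.69 ± 0.37) and PDK4 (a kinase that restrains pyruvate oxidation, -2.53 ± 0.30). Of the matrix proteases and remodelling genes 13 of 20 rose and 3 fell (median 0.68, camera adjusted p = 6.04e-05, and adjusted p = 0.1 with an estimated correlation), with TIMP3 at 2.27 ± 0.18 and MMP19 at 1.67 ± 0.13.

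Among genes of lipid metabolism, 15 of 19 measured members of the cholesterol synthesis list rose with 4F and 0 fell, or 16 adjusted over the list alone (median 0.74, adjusted p = 1.63e-13, and adjusted p = 0.0433 with an estimated correlation). MSMO1 rose by 3.0 ± 0.14, SC5D by 1.88 ± 0.11 and ACAT2 by 1.99 ± 0.13. Of the fatty acid and PPAR list 12 of 23 rose and 3 fell (median 0.37, adjusted p = 0.000493, and 0.148 with an estimated correlation), with the desaturase FADS1 at 1.89 ± 0.15. Of the cholesterol efflux and LXR target list 8 of 18 rose and 4 fell (median 0.31, adjusted p = 0.0157, and 0.184 with an estimated correlation). Of the markers of mature macrophages 16 of 26 rose and 1 fell (median 0.80, adjusted p = 1.46e-07, and adjusted p = 0.0433 with an estimated correlation), among them the lipid-sensing receptor TREM2 (2.27 ± 0.22), MMP9 (1.24 ± 0.13) and the fatty acid carrier FABP4 (2.72 ± 0.36).

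Organelle and stress genes also rose with 4F without LPS. In the mitochondrial respiratory chain list 19 of 23 members rose (median 0.65, adjusted p = 1.06e-10, and 0.202 with an estimated correlation), with NDUFV1 at 0.79 ± 0.09 and NDUFB9 at 1.20 ± 0.14. In the lysosomal list 14 of 23 rose (median 0.41, adjusted p = 1.46e-07, and 0.177 with an estimated correlation), with the proton pump subunits ATP6V1H at 1.27 ± 0.11 and ATP6V0D2 at 2.25 ± 0.19. With the median of the olfactory receptor genes as a covariate, the lysosomal median was 0.25. Of 10 genes of the metal-binding metallothionein list 8 rose (median 1.39, adjusted p = 8.38e-07, and 0.177 with an estimated correlation), with MT2A at 1.43 ± 0.09 and MT1G at 2.27 ± 0.17. In the NRF2 and antioxidant list 13 of 21 rose and 1 fell (median 0.38, adjusted p = 1.22e-05, and 0.148 with an estimated correlation), with GCLC, which makes a glutathione precursor, at 2.12 ± 0.26. Ribosomal protein genes fell in 13 of 24 cases (median -0.24, adjusted p = 1.10e-05, and 0.152 with an estimated correlation), with RPS25 at -0.63 ± 0.06, and immediate early genes in 9 of 18 with 2 higher (median -0.39, adjusted p = 0.00141, and 0.327 with an estimated correlation), with ZFP36 at -1.01 ± 0.16.

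The Toll-like receptor genes, a family of the pattern recognition receptors named in the title, were not called as a group with 4F in the absence of LPS (median -0.02, adjusted p = 0.405, 8 of 10 members measured). TLR1 rose by 0.85 ± 0.21 (adjusted p = 0.00696), TLR6 by 0.74 ± 0.17 (adjusted p = 0.00360) and TLR3 by 0.29 ± 0.10 (adjusted p = 0.0346), 3 higher and 1 lower adjusted over the list alone. TLR2 (-0.21 ± 0.26), TLR4 (-0.10 ± 0.13), TLR7 (-0.13 ± 0.21), TLR8 (0.06 ± 0.12) and TLR9 (-0.26 ± 0.10) did not pass the threshold over all genes. LY96, which pairs with TLR4 to bind LPS, was higher by 1.02 ± 0.17 (adjusted p = 0.000299). CD14, which hands LPS to that pair, was at -0.85 ± 0.27 (adjusted p = 0.0282), and the adaptor MYD88 was at 0.24 ± 0.11 without a call. The TLR3 call was lost without control replicate 1, 3 or 4 or 4F replicate 2, 3 or 4 (adjusted p from 0.0566 to 0.0959). The CD14 call was lost without control replicate 1 or 3 or 4F replicate 2, 3 or 4 (adjusted p from 0.0528 to 0.0683). Its SE rests on the spread shared by all groups, and the SD of CD14 was 0.88 in 4F+LPS, against 0.07 in 4F and 0.11 in control. TLR9 passed without control+LPS replicate 2 or 4 or 4F+LPS replicate 1 or 2 (adjusted p from 0.0241 to 0.0495). After quantile normalization TLR6 was at 0.78 with an adjusted p of 0.142.

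Other receptor genes rose singly with 4F: the scavenger receptor MSR1 by 2.95 ± 0.25, the beta-glucan receptor CLEC7A by 1.08 ± 0.11, CLEC5A by 2.13 ± 0.30, the NOD signalling kinase RIPK2 by 1.07 ± 0.18 and the inflammasome adaptor PYCARD by 1.02 ± 0.18, while CD163L1 was at -1.57 ± 0.18. The C-type lectin list (adjusted p = 0.732), the scavenger receptor list (adjusted p = 0.963) and the NOD-like receptor list (adjusted p = 0.250) were not called. Among cytokines CCL7 rose by 1.86 ± 0.14, while IL1B (-1.11 ± 0.10) and CXCL8 (-0.83 ± 0.09) were lower, and the list was not called (4 of 34 higher, 4 lower, adjusted p = 0.715). Of the interferon-stimulated genes 18 of 34 rose and 2 fell (median 0.32, adjusted p = 8.25e-07, and adjusted p = 0.260 with an estimated correlation), with IFI6 at 1.93 ± 0.12 and SAMD9L at 1.23 ± 0.09.

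T cell markers were lower with 4F. Of 14 T cell markers 13 fell and 0 rose, or 14 lower adjusted over the list alone (median -0.78, adjusted p = 5.37e-10, and adjusted p = 0.0433 with an estimated correlation), with CD3E at -1.51 ± 0.12 and CD3D at -1.41 ± 0.12. The NK cell list (3 of 11 lower, adjusted p = 0.0682) and the B cell list (3 of 9 lower, adjusted p = 0.0664) were not called. In all, limma called 5469 genes, 2960 higher and 2509 lower, with 336 higher and 109 lower at least 2-fold. With each array centred on its median the split was 3502 higher and 1505 lower, and after quantile normalization 2155 higher and 850 lower. The fit of these 8 arrays alone called 8408 genes, and at least 1.5-fold 1430 were called.

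LPS in control cells, which measures the response that 4F could alter, raised interferon-stimulated and cytokine genes. RSAD2 (viperin, an antiviral protein) rose by 5.75 ± 0.16 (adjusted p = 1.72e-13), TNFAIP6 by 5.64 ± 0.17, IFIT1 by 5.14 ± 0.15, ITGB8 by 4.78 ± 0.14 and the metallothionein MT1M by 4.58 ± 0.41. The largest decreases were in MPEG1 (perforin-2, -3.66 ± 0.77), FUCA1 (a lysosomal fucosidase, -3.18 ± 0.60) and CLC (galectin-10, -2.69 ± 0.46). All 34 interferon-stimulated genes rose (median 3.20, camera adjusted p = 1.74e-33). All 24 genes of the NF-kB list rose (median 0.94, adjusted p = 4.68e-13), with RELA at 1.77 ± 0.08. Of 34 cytokine genes 28 rose and 1 fell (median 1.20, adjusted p = 1.22e-08), with CCL8 at 3.24 ± 0.19. All 24 ribosomal protein genes fell (median -0.92, adjusted p = 4.68e-13), with RPL7 at -1.31 ± 0.08. With an estimated correlation these lists each had an adjusted p of 0.0298.

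Of the Toll-like receptor genes, TLR8 (1.90 ± 0.12), TLR2 (1.86 ± 0.26), TLR3 (1.56 ± 0.10), TLR1 (1.40 ± 0.21) and TLR6 (0.90 ± 0.17) rose with LPS in control cells, TLR9 was lower at -0.46 ± 0.10, and TLR4 (-0.04 ± 0.13) and TLR7 (-0.06 ± 0.21) were not called. The list had a median of 1.15 (adjusted p = 0.0257, and adjusted p = 0.248 with an estimated correlation). With the median of olfactory receptor genes on each array as a covariate, a setting chosen after the data were seen, it was at 0.48 (adjusted p = 0.0849). MYD88 rose by 1.08 ± 0.11, and CD14 (0.32 ± 0.27) and LY96 (-0.10 ± 0.17) did not pass. Of 11 cytosolic nucleic acid sensors 9 rose (median 1.94, adjusted p = 6.75e-08, and 0.0707 with an estimated correlation), with EIF2AK2 at 3.36 ± 0.09 and DHX58 at 2.81 ± 0.10. The costimulatory gene CD80 rose by 3.15 ± 0.13 and the lectin CLEC10A was at -1.77 ± 0.07. Of 9 B cell markers 8 fell (median -0.66, adjusted p = 0.00104, and 0.0405 with an estimated correlation), with MS4A1 at -2.31 ± 0.22. In all 11689 genes were called, 5198 higher and 6491 lower, with 1043 higher and 112 lower at least 2-fold. The split turned to 5880 higher and 4501 lower with arrays centred on their median, and to 2119 higher and 497 lower after quantile normalization. At least 1.5-fold, 3165 were called.

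**Figure D1:**
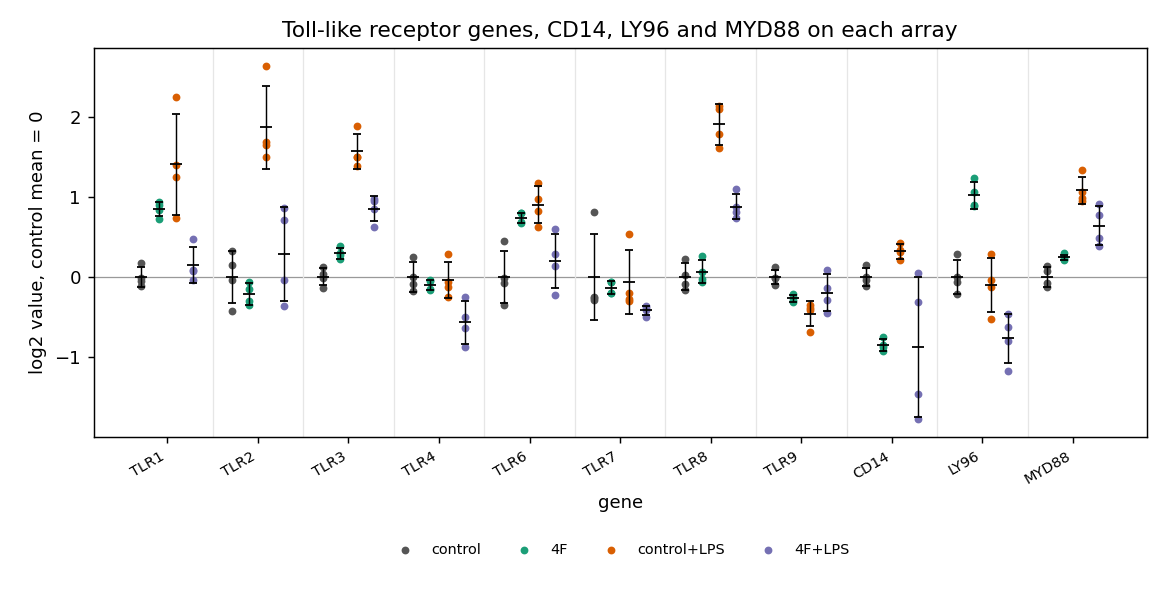
Log2 value on each array, relative to the control mean, for the 8 measured Toll-like receptor genes, CD14, LY96 and MYD88, with 4 arrays per group as points and the group mean ± SD as black bars. TLR8 had a mean of 1.90 in control+LPS and 0.88 in 4F+LPS, and CD14 had an SD of 0.88 in 4F+LPS and 0.09 in control+LPS.

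Under LPS, NF-kB genes, cytosolic nucleic acid sensors and most Toll-like receptor signalling genes were lower in cells grown with 4F than in cells grown without it. The largest decreases were in CRLF2 (a cytokine receptor, -2.66 ± 0.23, adjusted p = 5.06e-07), ACOD1 (which makes itaconate, -2.47 ± 0.44), MMP12 (-2.44 ± 0.62), VCAN (versican, -2.33 ± 0.34) and CCL20 (-2.33 ± 0.16). All 24 NF-kB list genes were lower (median -0.83, camera adjusted p = 5.47e-09, and 0.279 with an estimated correlation), with TNIP3 at -2.13 ± 0.17 and TRAF1 at -1.26 ± 0.10. All 11 cytosolic nucleic acid sensors were lower (median -0.75, adjusted p = 9.94e-05, and 0.279 with an estimated correlation), with CGAS at -1.62 ± 0.13. Of 24 Toll-like receptor adaptors and signalling genes 19 were lower and 0 higher (median -0.53, adjusted p = 0.000272, and 0.279 with an estimated correlation), with IRAK2 at -1.36 ± 0.10 and TBK1 at -1.12 ± 0.13. Of 19 NOD-like receptor and inflammasome genes 13 were lower (median -0.52, adjusted p = 0.00511, and 0.279 with an estimated correlation), with NOD2 at -0.94 ± 0.10. Of 34 cytokine genes 19 were lower and 1 higher (median -0.49, adjusted p = 0.00504, and 0.279 with an estimated correlation), with PTGS2 at -2.08 ± 0.32. The C-type lectin list (7 higher and 4 lower of 19, median 0.09, adjusted p = 0.444) and the scavenger receptor list (7 higher and 7 lower of 23, median 0.03, adjusted p = 0.491) were not called. With an estimated correlation none of the 35 lists was called, the smallest adjusted p being 0.279. Without 4F+LPS replicates 3 and 4 or replicates 1 and 2, a split chosen after the data were seen, the values were MMP12 at -0.71 and -4.17 and ACOD1 at -3.18 and -1.76.

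TLR2 (-1.57 ± 0.26, adjusted p = 0.000104), TLR1 (-1.25 ± 0.21), TLR8 (-1.03 ± 0.12), TLR3 (-0.72 ± 0.10), TLR6 (-0.70 ± 0.17) and TLR4 (-0.53 ± 0.13, adjusted p = 0.00202) were lower with 4F under LPS. TLR9 was higher at 0.26 ± 0.10 (adjusted p = 0.0277), a call lost without control+LPS replicate 2 (0.109), 4F+LPS replicate 2 (0.109) or 4F+LPS replicate 3 (0.0635). TLR7 was at -0.35 ± 0.21 without a call, and passed without control replicate 3 (0.0318). The list median was -0.71 (adjusted p = 0.0306, and adjusted p = 0.295 with an estimated correlation). CD14 (-1.19 ± 0.27), LY96 (-0.66 ± 0.17) and MYD88 (-0.44 ± 0.11) were lower. CD14 differed between pairs of 4F+LPS arrays, with -1.93 without replicates 3 and 4 and -0.45 without replicates 1 and 2. After quantile normalization the calls of TLR2 (-0.77), TLR3 (-0.06), TLR4 (-0.44), TLR6 (-0.33), TLR8 (-0.24), LY96 (-0.50), MYD88 and TLR9 were lost. That step forced 1 distribution on centred values whose spread over all genes was 0.12 in control, 0.58 in control+LPS and 0.40 in 4F+LPS. It widens the control values and can take out differences among high ones, so these lost calls do not show that the changes were gone.

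Olfactory receptor genes, best known from the nose, moved the other way. Of 339 such genes, used here as a technical measure, 322 were higher with 4F under LPS and 0 lower (median 0.60). Of all 18353 genes 6028 were higher and 6532 lower. The class made up 1.85% of the genes tested but 23 of the 48 genes at least 2-fold higher, among them OR4K2 (1.62 ± 0.19). With LPS in control cells 251 of the 339 fell and 1 rose (median -0.35). Of 10 fibroblast markers 8 were higher with 4F under LPS (median 0.34, adjusted p = 0.00511, and 0.279 with an estimated correlation), with COL1A2 at 0.71 ± 0.09. With the olfactory receptor covariate the Toll-like receptor list turned to 0.11 (adjusted p = 0.756) and no receptor gene kept its call. TLR1 turned to 0.29, TLR4 to 0.18, TLR6 to 0.05, MYD88 to 0.22 and MMP12 to 0.79. TLR2 was at -1.27, TLR3 at -0.18, TLR8 at -1.15, TLR9 at 0.55, CD14 at -2.34 and LY96 at -0.30, and the median SE over all genes rose from 0.09 to 0.21, so a lost call alone does not show that a change was gone. The NF-kB list stayed lower at -0.61 and the cytokine list at -0.75, both past the threshold, with ranges of -0.70 to -0.54 and -0.98 to -0.50 with 1 array left out. The nucleic acid sensors were at -0.31 (adjusted p = 0.00241), while the adaptor list at -0.13 (0.0558) and the NOD-like receptor list at -0.11 (0.204) lost their calls. The covariate did not overlap between control+LPS (-0.58 to -0.18) and 4F+LPS (0.10 to 0.39). A kept call therefore does not exclude a difference in signal range between arrays. Of 34 interferon-stimulated genes 33 were lower (median -0.70, adjusted p = 3.25e-08, and 0.279 with an estimated correlation), with OASL at -1.18 ± 0.14. This list was at -0.31 with the covariate, from -0.46 to -0.03 with 1 array left out, and turned to 0.06 after quantile normalization (adjusted p = 0.144). That normalization gives every array the same distribution of centred values, and this list was high in control+LPS (3.20) and 4F+LPS (2.39). It can thus take out a difference among the highest values, so the 0.06 does not show that the change was gone.

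**Figure D2:**
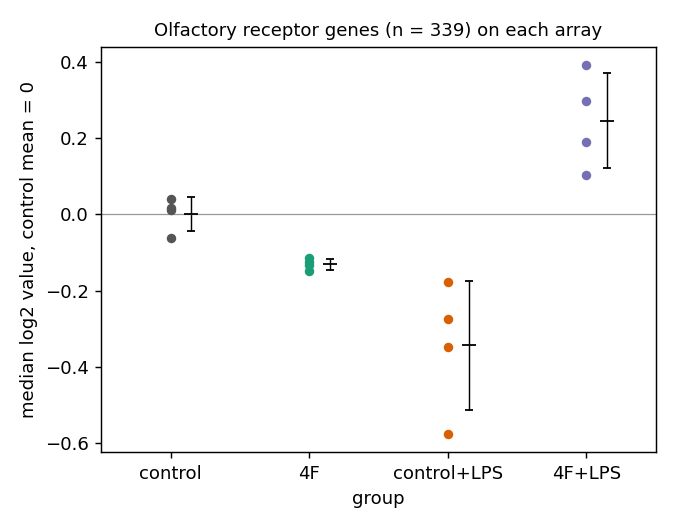
Median log2 value of 339 olfactory receptor genes on each array, relative to the control mean, by group, with 4 arrays per group as points and the mean ± SD in black. The control+LPS arrays lie from -0.58 to -0.18 and the 4F+LPS arrays from 0.10 to 0.39.

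Metabolic genes were also lower with 4F under LPS: 15 of 19 cholesterol synthesis genes (median -0.57, adjusted p = 0.000653, and 0.279 with an estimated correlation), with MSMO1 at -1.24 ± 0.14, and 19 of 25 glycolysis and hypoxia genes (median -0.57, adjusted p = 0.00104, and 0.279 with an estimated correlation), with PFKFB3 at -1.42 ± 0.16. With the olfactory receptor covariate the glycolysis list lost its call at -0.0073 (adjusted p = 0.393), and the cholesterol synthesis list was at -0.20 (0.0208), from -0.42 to -0.03 with 1 array left out. The 4F+LPS arrays differed by pairs here too. Without replicates 3 and 4 or replicates 1 and 2 the cholesterol synthesis list was at -0.35 and -0.71 and the glycolysis list at -0.30 and -0.75. The respiratory chain list (13 of 23 lower, median -0.37, adjusted p = 0.00588, and 0.549 with an estimated correlation) was at -0.10 (adjusted p = 0.403) and -0.71. The mature macrophage list (median -0.43, adjusted p = 0.0633) was at -0.19 and -0.61 and passed without replicates 1 and 2 (adjusted p = 0.0153). The comparison called 12560 genes, 6028 higher and 6532 lower, with 48 higher and 500 lower at least 2-fold. Quantile normalization gave 906 higher and 2907 lower, and centring on the median 4898 higher and 7109 lower. At least 1.5-fold 3528 genes were called, and with the covariate 64, where the median SE was 0.21 against 0.09.

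In 4F cells LPS also raised the interferon-stimulated genes, and most cholesterol synthesis genes and mature macrophage markers fell. RSAD2 rose by 4.58 ± 0.16 (adjusted p = 6.85e-12), IFIT1 by 4.40 ± 0.15, THBS1 by 3.91 ± 0.41 and ITGB8 by 3.76 ± 0.14. The largest decreases were in FABP4 (-4.60 ± 0.36), CD36 (a receptor for oxidized lipoprotein, -3.85 ± 0.28), FN1 (-3.79 ± 0.64), TREM2 (-3.36 ± 0.22) and FBP1 (-3.23 ± 0.61). All 34 interferon-stimulated genes rose (median 1.99, camera adjusted p = 1.87e-33, and 0.0340 with an estimated correlation). Of 24 NF-kB genes 11 rose and 1 fell (median 0.19, adjusted p = 0.00430, and 0.323 with an estimated correlation). The respiratory chain list fell in 22 of 23 members (median -0.88, adjusted p = 8.54e-13, and 0.159 with an estimated correlation). The cholesterol synthesis list fell in 15 of 19 with 1 higher (median -0.75, adjusted p = 1.85e-07, and 0.0831 with an estimated correlation). Mature macrophage markers fell in 15 of 26 cases with 1 higher (median -0.80, adjusted p = 7.56e-05, and 0.0831 with an estimated correlation), the higher one being NUPR1 (2.42 ± 0.13). T cell markers rose in 10 of 14 cases and fell in 0 (median 0.48, adjusted p = 0.000161, and 0.147 with an estimated correlation), with CD2 at 1.03 ± 0.15 and CD6 at 0.63 ± 0.07. Ribosomal protein genes fell in 23 of 24 cases (median -0.64, adjusted p = 2.08e-15, and 0.0340 with an estimated correlation). The 4F+LPS arrays were far apart for FN1 (SD 1.96) and FBP1 (SD 1.74). Without 4F+LPS replicates 3 and 4 or replicates 1 and 2 the values were FN1 at -2.10 and -5.49 and FBP1 at -1.73 and -4.73, and the respiratory chain list at -0.70 and -1.22 and the cholesterol synthesis list at -0.48 and -0.96. Olfactory receptor genes were higher in 260 of 339 cases (median 0.37).

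TLR8 (0.81 ± 0.12) and TLR3 (0.55 ± 0.10) rose with LPS in 4F cells, and TLR1 (-0.70 ± 0.21), TLR6 (-0.54 ± 0.17) and TLR4 (-0.47 ± 0.13) were lower. TLR2 (0.50 ± 0.26), TLR7 (-0.28 ± 0.21) and TLR9 (0.07 ± 0.10) did not pass, nor did the list (median -0.11, adjusted p = 0.902). TLR6 lost its call without 4F+LPS replicate 3 (-0.40, adjusted p = 0.0642), and TLR2 passed without 4F+LPS replicate 2 (0.72, adjusted p = 0.0340). With the covariate TLR1 turned to 0.29. LY96 was lower at -1.78 ± 0.17, MYD88 rose by 0.40 ± 0.11 and CD14 was at -0.03 ± 0.27, or -0.77 and 0.71 without 4F+LPS replicates 3 and 4 or 1 and 2. This comparison called 7648 genes, 3612 higher and 4036 lower, with 126 higher and 579 lower at least 2-fold. The split was 1250 higher and 3141 lower after quantile normalization, and 2234 genes were called at least 1.5-fold.

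**Figure D3:**
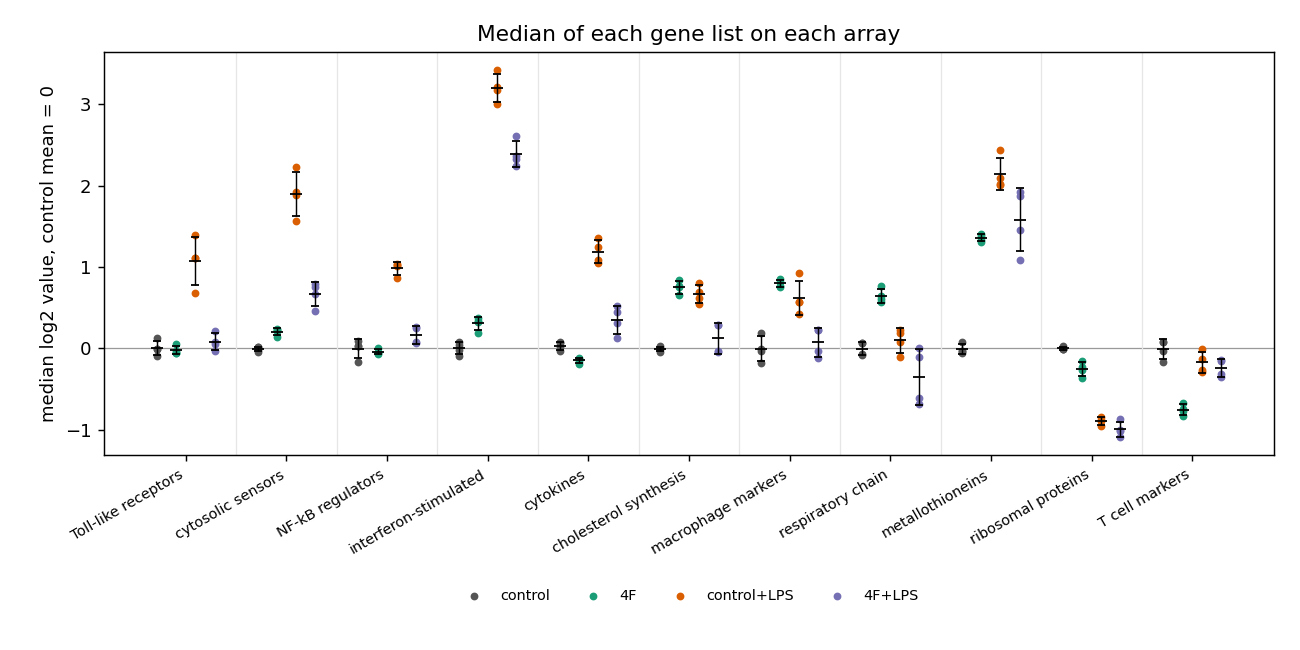
Median log2 value of gene lists on each array, relative to the control mean, with 4 arrays per group as points and the group mean ± SD as black bars. The interferon-stimulated list had a mean of 3.20 in control+LPS and 2.39 in 4F+LPS, and the NF-kB list 0.98 and 0.17.

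Whether 4F changed the LPS response was tested as the difference of the responses in 4F and control cells. SPP1 (-6.40 ± 1.23, adjusted p = 0.000322), FN1 (-6.29 ± 0.91), MMP12 (-5.97 ± 0.88), CHIT1 (-5.91 ± 1.01) and MMP7 (-4.52 ± 0.99) had the most negative differences, and PDK4 (2.85 ± 0.43) and PPBP (2.60 ± 0.36) the most positive. Without 4F+LPS replicates 3 and 4 or replicates 1 and 2 the differences were SPP1 at -4.24 and -8.56, FN1 at -4.59 and -7.99, MMP12 at -4.24 and -7.71, CHIT1 at -4.16 and -7.66 and MMP7 at -2.62 and -6.42. The response was lower in 4F cells for TLR1 (-2.10 ± 0.30), TLR6 (-1.44 ± 0.24), TLR2 (-1.36 ± 0.37), TLR8 (-1.09 ± 0.17), TLR3 (-1.01 ± 0.14), LY96 (-1.68 ± 0.23) and MYD88 (-0.69 ± 0.15), and higher for TLR9 (0.53 ± 0.14). TLR7 (-0.22 ± 0.30) and CD14 (-0.35 ± 0.39) did not pass, and TLR7 passed without control replicate 3 (-0.49, adjusted p = 0.0417). TLR4 (-0.43 ± 0.18, adjusted p = 0.0456) kept its call only without control replicate 3, control+LPS replicate 3, 4F+LPS replicate 1 or 4F+LPS replicate 2, and lost it without any 1 of the other 12 arrays (adjusted p from 0.0502 to 0.102). With the covariate TLR4 turned to 0.45 and MYD88 to 0.13. In the cholesterol synthesis list 16 of 19 members had a lower response and 1 a higher one (median -1.30, camera adjusted p = 2.26e-07), with MSMO1 at -4.23 ± 0.20. Of 35 lists 25 differed, and none with an estimated correlation, the smallest adjusted p being 0.200. Olfactory receptor genes had a higher response in 315 of 339 cases (median 0.73). The test called 12978 genes, 6737 higher and 6241 lower, against 1488 higher and 4032 lower after quantile normalization, and 301 with the olfactory receptor covariate.

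Across 18353 genes, which are not independent replicates, the fold changes of 4F without and with LPS, which share no array, had a Pearson r of -0.42 and a Spearman rho of -0.51. Of the genes called in both, 489 changed in the same direction and 3594 in opposite ones. Over all alternatives r lay between -0.53 and -0.19, the latter with the olfactory receptor covariate, and the 489 became 20 with the covariate and 847 with array weights. Genes higher without LPS and lower with it numbered 2297, against 1053.5 for independent lists, and genes higher in both numbered 49, against 972.2. This was 1 of 2 such relations computed. The other, LPS in control cells against LPS in 4F cells, gave r = 0.01 and rho = -0.31, with 1333 genes in the same direction and 3763 in opposite ones.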

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

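The tests of signal range on the Toll-like receptor list, of uniform compression, of donors, of lymphocyte transcripts and of background signal were chosen after the result was seen. The counts over other splits of the arrays were not. For the NF-kB list the prediction was written beforehand, but its olfactory receptor covariate was chosen after the data were seen.

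The test of the difference of LPS responses passed for 25 of 35 gene lists and 9 of 11 receptor genes. With an estimated correlation none of the lists passed, the smallest adjusted p being 0.200. The median difference was lower in 4F cells for Toll-like receptors (-1.05), their adaptors (-0.66), NOD-like receptors (-0.60), cytosolic nucleic acid sensors (-0.82), Fc and complement receptors (-0.84), cytokines (-0.34), NF-kB genes (-0.80) and interferon-stimulated genes (-1.07). It was also lower for cholesterol synthesis (-1.30), cholesterol efflux (-0.58), fatty acid genes (-0.65), mature macrophage markers (-1.25), NRF2 genes (-0.61), metallothioneins (-1.76), endoplasmic reticulum stress (-0.69), lysosomal genes (-0.59), glycolysis (-0.87), proliferation (-0.75), matrix proteases (-1.30) and the respiratory chain (-1.06). It was higher for markers of T cells (0.54), platelets (0.45), erythroid cells (0.60), neutrophils (0.53) and fibroblasts (0.59). Among receptor genes the differences were -2.10 for TLR1, -1.36 for TLR2, -1.01 for TLR3, -0.43 for TLR4, -1.44 for TLR6, -1.09 for TLR8, 0.53 for TLR9, -1.68 for LY96 and -0.69 for MYD88. The 4F+LPS arrays split in pairs for some lists: without replicates 3 and 4 or replicates 1 and 2 the difference was -0.32 (adjusted p = 0.172) and -1.07 for proliferation and -0.69 and -1.35 for the respiratory chain. Calls were also lost for cholesterol efflux without replicates 3 and 4 (-0.77, adjusted p = 0.0576), and without replicates 1 and 2 for Toll-like receptors (-0.97, 0.0699) and cytokines (-0.33, 0.189; -0.69 without 3 and 4). With the olfactory receptor covariate the Toll-like receptor list was at -0.28, adaptors at -0.18, NOD-like receptors at -0.21, cholesterol efflux at -0.15, fatty acid genes at -0.42 and markers of platelets, erythroid cells, neutrophils and fibroblasts at 0.20, 0.43, 0.23 and 0.20, and these lists lost their calls. The other lists above kept their direction and call, with nucleic acid sensors at -0.25, interferon-stimulated genes at -0.47, glycolysis at -0.39, NF-kB genes at -0.55 and cytokines at -0.79. Cytokines, metallothioneins (-2.06) and T cell markers (0.63) grew in size and the rest shrank. Among the latter were endoplasmic reticulum stress at -0.26, lysosomal genes at -0.30, NRF2 genes at -0.36, the respiratory chain at -0.55 and matrix proteases at -0.67.

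NF-kB and Toll-like receptor genes were lower with 4F under LPS while olfactory receptor genes were higher, which a difference in signal range between arrays could produce. With the olfactory receptor median as a covariate the NF-kB list median was -0.61 against -0.83 (-0.70 to -0.54 with 1 array left out). The Toll-like receptor list went from -0.71 to 0.11 (-0.12 to 0.22 with 1 array left out), and the covariate also raised the median SE from 0.09 to 0.21. The olfactory receptor medians did not overlap between control+LPS (-0.58 to -0.18) and 4F+LPS (0.10 to 0.39). The covariate therefore extends a slope found within groups across that gap. It cannot tell signal range from 4F, so signal range stays open for both lists. One uniform compression of all changes from control would leave the same ratio of the 4F+LPS level to the control+LPS level, both against control, but that ratio was larger by 0.575 for interferon-stimulated than for NF-kB genes (74.5% and 17.1%). It includes the rise of interferon-stimulated genes with 4F before LPS; the LPS responses alone were 1.99 in 4F and 3.20 in control cells for these, and 0.19 and 0.94 for NF-kB genes. An effect of 4F on the NF-kB genes remains a hypothesis, since signal range and donors that differ between groups stay open.

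Donors that differ between the groups could also give many called genes, as the labels do not state the donors. The 13 genes with common inherited differences between people had a median absolute log2 fold change of 0.44 with 4F without LPS, at percentile 99.9 of random gene sets. Such donors would give this, and so would a response of these genes to the treatment. With 4F under LPS they were at percentile 64.8, which leaves donors open there. For LPS in control cells they were at percentile 100, for LPS in 4F cells at 24.1 and for the difference at 97.7. The random sets were drawn from all genes, whatever their response, so the percentile cannot tell donors from a response to 4F or LPS. Of the 35 splits of the 8 arrays, 1 called as many genes as the real one, the real split itself, for 4F without LPS (5469, highest other 0), 4F with LPS (12560, highest other 7511), LPS in control cells (11689, highest other 6) and LPS in 4F cells (7648, highest other 0). For the difference 1 of 100 assignments did (12978, highest other 6678). The real grouping thus called more genes than any other grouping counted. These counts exchange arrays that may differ only technically, so they cannot exclude chance differences between cultures or donors. The split with 7511 exchanged only 1 array of each group, so its count still holds much of the group difference.

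T cell markers were lower with 4F without LPS, for which fewer carried-over lymphocytes may be a source. Of 17 abundant lymphocyte transcripts 13 were called lower, which is 76.5%, but 10 of the 17 are T cell genes, all called lower, which restate the pattern and test nothing. Of the other 7, KLRB1, MS4A1 and CD79B were called lower and GZMA (0.02), NKG7, GNLY and CD79A were not, so these genes neither showed nor excluded fewer lymphocytes. With 4F under LPS only 3 of 14 T cell markers were lower (median -0.14, camera adjusted p = 0.444). Those cells were also grown with 4F for 7 days. LPS itself moved these markers, however, with list medians of -0.19 in control cells and 0.48 in 4F cells. The cultures may also have differed between the groups. The LPS arrays therefore cannot tell whether T cells were lost during growth with 4F. A lower background signal was argued against, as 0 of 10000 random sets of olfactory receptor genes had a median as low as -0.78 (range -0.29 to 0.0031).

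Some arrays lay apart from the other 3 of their group by Dixon's test, with the gap as a share of the group's range in parentheses. These were control replicate 3 for scavenger receptors (0.875) and for the spread over all genes (0.914), control replicate 1 for metallothioneins (0.851) and control replicate 4 for ribosomal proteins (0.850). They were also control+LPS replicate 3 for NF-kB genes (0.879) and cholesterol efflux genes (0.855), control+LPS replicate 1 for alternative activation markers (0.836), 4F+LPS replicate 3 for scavenger receptors (0.830) and 4F+LPS replicate 1 for neutrophil markers (0.915). These are 9 of 152 combinations of group and measure, and chance gives about 7.6.

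Probe sets outside the comparisons also changed. Of 1752 that name several genes 656 were called with 4F without LPS and 1240 with LPS in control cells, and of 7807 unnamed here 921 and 3619.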

How the results depend on the processing

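The olfactory receptor covariate, leaving out 4F+LPS replicates in pairs and camera over the listed genes only were chosen after the data were seen; the cause was not tested for changes below unless named. Values are centred, so a stricter filter on dim genes, the pseudocount of 16 and signal over background could not be had, and no filter and the mean of probe sets are the values reported. Same-numbered arrays of different groups had residual correlations from -0.14 to 0.36, and 6 of 16 arrays were closest to their own number, so numbers were not taken as pairs. Between control+LPS and 4F+LPS these correlations were 0.36, 0.05, 0.12 and 0.36 for replicates 1 to 4. A pairing within the LPS groups is therefore not excluded. With the number as a block, counts were 5485, 12450, 11552, 7494 and 12841, in the order 4F without LPS (5469), 4F with LPS (12560), LPS in control cells (11689), LPS in 4F cells (7648) and the difference (12978). With 1 array left out they ranged from 4040 to 6157, 11324 to 12906, 10231 to 12078, 6184 to 8249 and 12230 to 13354. The 489 genes changed alike by 4F ranged from 357 to 558, and r from -0.47 to -0.36. The lists called ranged from 19 to 22, 17 to 21, 16 to 19, 15 to 19 and 23 to 25. The Toll-like receptor median ranged from -0.80 to -0.61 with LPS and from -0.06 to 0.14 without, where no alternative gave a call.

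Quantile normalization gave 3005, 3813, 2616, 4391 and 5520 genes in that order, 163 changed alike, r = -0.30, 8 lists for 4F with LPS, 16 for the difference, and a Toll-like receptor median of -0.32 with LPS. It forces the narrow control arrays to the spread of the others, and also evens out the spread of control+LPS (0.58) and 4F+LPS (0.40). A 1.5-fold minimum, which removes small changes, gave 1430, 3528, 3165, 2234 and 6559, and 67 changed alike. An adjusted p under 0.01 gave 2975 for 4F without LPS, 4715 for LPS in 4F cells and 209 changed alike. The covariate gave 64, 4028, 2065 and 301 for the last 4 comparisons, 20 changed alike, r = -0.19, 11 lists for 4F with LPS and a Toll-like receptor median of 0.11. For 4F without LPS the fit of those arrays alone gave 8408 and array weights 8909, and weights gave 847 changed alike. Without 4F+LPS replicates 3 and 4 LPS in 4F cells gave 5067 and r was -0.24, and without replicates 1 and 2 the Toll-like receptor median with LPS was -0.86 (adjusted p = 0.0531). Camera with an estimated correlation called 3, 0, 5, 2 and 0 lists (Toll-like receptors with LPS -0.71, adjusted p = 0.295), and over the listed genes only 12 for 4F without LPS and 12 for LPS in 4F cells (Toll-like receptors with LPS -0.71, adjusted p = 0.366). Fry, which tests no contrast with other genes, called 29 for 4F with LPS and 27 for LPS in control cells.

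Among results called in either setting, directions turned as follows; lists called in neither also changed sign with the covariate, among them mature macrophage markers with 4F under LPS (-0.43 to 0.10). With the covariate, 4F with LPS gave 0.11 for the Toll-like receptor list, 0.29 for TLR1, 0.18 for TLR4, 0.045 for TLR6, 0.22 for MYD88, 0.79 for MMP12 and 0.056 for lysosomal genes. LPS in 4F cells gave 0.29 for TLR1, and the difference 0.45 for TLR4 and 0.13 for MYD88. Quantile normalization gave 0.061 for interferon-stimulated genes with 4F under LPS. Without 4F+LPS replicates 1 and 2 CD14 was at 0.71 for LPS in 4F cells and 0.39 for the difference, and without 3 and 4 proliferation was at 0.090 for LPS in 4F cells. Of 2368 values of named genes with 1 array left out 2334 kept direction and call, 27 lost the call and 7 gained it. Of 1332 under other alternatives 1208, 97 and 17 did so and 10 turned. For lists these were 2715, 51 and 34 of 2800, and 1759, 227 and 110 of 2100 with 4 turned.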

Other observations

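The gene classes below were chosen after a first look at the values. Of 175 small nucleolar RNA genes 105 were lower with 4F without LPS and 0 higher (median -0.45), and with LPS in control cells 97 were lower and 4 higher (median -0.33). With 4F under LPS 29 were higher and 32 lower (median -0.06). Keratin-associated protein genes, which build hair, moved with the olfactory receptor genes: 64 of 67 were higher with 4F under LPS (median 0.54) and 50 of 67 lower with LPS in control cells (median -0.36).

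Some lists not described with the comparisons above gave these medians with 4F without LPS and with LPS: Fc and complement receptors 0.24 (adjusted p = 0.0290) and -0.37 (0.0194), monocyte markers -0.16 (0.478) and -0.66 (0.0194), and alternative activation markers 0.13 (0.138) and -0.01 (0.987). MHC class II and costimulation genes gave 0.08 (0.870) and -0.15 (0.0825), dendritic cell markers -0.10 (0.715) and 0.06 (0.491), endoplasmic reticulum stress genes 0.21 (0.0400) and -0.45 (0.00511), and proliferation genes 0.34 (0.0110) and -0.38 (0.115). Platelet markers gave -0.22 (0.0162) and 0.25 (0.167), erythroid markers -0.25 (0.0189) and 0.31 (0.0323), and neutrophil markers -0.22 (0.0653) and 0.32 (0.0497). None of these was called with an estimated correlation in either comparison. With the olfactory receptor covariate, 4F under LPS gave -0.20 for endoplasmic reticulum stress genes (-0.32 to 0.05 with 1 array left out) and -0.25 for Fc and complement receptors. It gave 0.20 for erythroid, 0.15 for neutrophil and -0.81 for monocyte markers. Without LPS the Fc and complement receptors were at 0.10 and endoplasmic reticulum stress genes at 0.16.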
